A study of Mus musculus with 40 samples.

How the data were processed

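The series measured RNA of 40 livers from C57BL/6J mice on 2-colour arrays, with 1 array per animal. Per the labels, the liver RNA carried Cy5 on every array and a pool of liver from 40 C57BL/6J mice carried Cy3, so that each value is a ratio of a liver to the same pool and no dye was swapped. The titles do not say that the pool held these same 40 livers, which was assumed here. The deposited value table holds log10 ratios for 23574 probes on each of the 40 arrays, with 0 missing values, and 0 of its columns were left unused. Values stop at 2 and at -2, that is at a 100-fold ratio, and 29 values on 16 probes lie at a limit. How the authors subtracted background, normalized and centred the ratios is not given in the sources used here. Scanner files were not used here, so signal over background was unknown and the number of arrays limits the precision.

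The base of the logarithm and the direction were settled from the values and the dyes. The Y-linked genes Eif2s3y and Kdm5d lay lower in all 20 females than in every male, as Cy5 over Cy3 requires. Read as log10, the male mean of Eif2s3y was 1.94-fold over the pool, against 1.22-fold read as log2 and 1.33-fold read as natural logs. A pool of equal parts of male and female liver allows at most a 2-fold ratio for the mean over all 20 males, while single groups lay at up to 2.17-fold. Across the 200 most variable probes the mean linear ratio to the pool had a median of 1 read as log10, 0.954 read as natural logs and 0.961 read as log2. A pool of the same livers, as assumed, would require a mean of 1. The array medians ran from -0.0135 to 0.0109, the means from -0.00382 to 0.00189 and the interquartile ranges from 0.0389 to 0.102, all in log10 units. Values were converted to log2 for every test, and differences are given on the log2 scale.

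Probe names came from the platform annotation and were kept only where the Entrez identifier is in the mouse RefSeq table. Of the 23574 probes, 13665 had 1 symbol, 48 had several and 9861 were not named in the annotation. A further 1003 of those with 1 symbol had an identifier outside the mouse table and were left unnamed, which left 12662 named probes of 10842 genes. A total of 1157 genes had over 1 probe. For these the probe with the largest SD over the 40 arrays stood for the gene, and of the 103 genes named by the rule below 13 had further probes, of which 10 had a probe of opposite sign or more than 3 times smaller. Such probes are given where a difference of the gene is reported, unless stated otherwise. No genome build came with the annotation, so no coordinates are given. The genes Xist, Ddx3y, Uty, Prlr and Cyp7a1 were not among the named probes and were not analysed here.

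Animals were grouped by the labels into 8 groups of 5: intact females and males, and ovariectomized females and castrated males with pellets of placebo, estradiol or dihydrotestosterone (DHT). Animal numbers are those of the labels, and each animal occurs in 1 group. A linear model with 8 group means was fitted to all 40 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, 32 residual degrees of freedom and 3.42 prior ones. The median residual SD per probe was 0.146. A total of 17 contrasts were tested, and within each a probe passed at a Benjamini-Hochberg adjusted p under 0.05. Each p is two-sided. No batch, slide or date was given in the labels, so none was tested.

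Groups of genes were fixed before the data were examined, as 38 lists of pathways, known sex-biased or hormone-responsive liver genes and cell type markers. The 35 lists with at least 3 measured genes were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 35 lists of a contrast, and again with the correlation estimated from the data. Over 595 tests, 85 passed with the preset correlation and 10 with an estimated one. Median, mean and test differed in sign for 95 of the 595, and for 0 of the 85 that passed. For each list, counts are given over all probes tested and adjusted over the list alone.

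Genes named in the text follow a rule fixed before the data were examined. For each of 8 main comparisons they are the 10 highest and 10 lowest genes among those that passed with 2 groups of 5 that did not overlap, a separation that chance gives to 0.79% of genes without any difference. For the other contrasts they are the 5 highest and 5 lowest, in interactions without the condition on overlap. To these come up to 4 members of each list discussed with the smallest adjusted p, the sex chromosome genes, and the hormone receptors Esr1 and Ghr. Clone names were left out.

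A score of the intact sex difference was computed per animal. Its probes were those that differed between intact females and males with an adjusted p under 0.05 by at least 1.5-fold, 161 higher in females and 299 higher in males. The score is the mean log2 ratio of the first set minus that of the second. It was compared between groups outside the intact animals with exact two-sided permutation tests over 5 comparisons, for which 5 animals against 5 can give a p no smaller than 0.0079. The macrophage score is the mean log2 ratio of 14 measured marker genes. The clock index is the mean of 9 clock genes of the Nr1d1 arm minus that of 5 of the Arntl arm, and both indices were compared with the same exact test over 9 comparisons.

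The fit was tested on simulated data for castration in males, with 23574 probes of which 200 were changed. It recovered 46 of 50 probes changed 1.5-fold and 50 of 50 at each of 2-, 3- and 5-fold, with 4 false calls and 0 in the wrong direction. The simulated noise was independent between probes and arrays, with 1 SD per probe, while residuals of real arrays correlated up to 0.69 (animals 3 and 26). These counts therefore test the fitting steps and do not give error rates for the real arrays. Arrays were compared within groups, and the most similar pair still differed with an SD of 0.161 log2 over all probes. Alternatives fixed before the data were examined were centring each array on its median, quantile normalization, a fit on only the groups of a contrast, means over all probes of a gene, a filter on flat probes, robust variance moderation, array weights, other thresholds for the score, an estimated correlation for the lists, and leaving out each animal in turn. Leaving out arrays of wide residual spread, a covariate for the clock index, the count of macrophage markers without 2 animals and the folds of genes without 1 animal were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.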

Results

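Gene expression was measured in the livers of 40 C57BL/6J mice, an inbred laboratory strain, in 8 groups of 5. The groups were intact females, intact males, and ovariectomized females or castrated males that carried a pellet of placebo, estradiol or dihydrotestosterone (DHT). Gonads were removed at 8 weeks of age, pellets were placed at 12 weeks and livers were taken at 14 weeks after a 12 h fast on chow with 4% fat. The estradiol pellet held 0.5 mg and gave about 300 pg/ml in plasma, and the DHT pellet held 5 mg and gave 1 to 2 ng/ml, both released over 21 days. The labels do not say whether intact mice carried a pellet. Each animal had 1 array of 23574 probes, read against a pool of 40 livers, and the median residual SD per probe was 0.146 on the log2 scale. Counts are of probes with an adjusted p under 0.05 in limma, each difference is a log2 difference of group means with its SE, and each group had 5 animals unless stated.

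The Y-linked gene Eif2s3y, a translation factor subunit, lay at 1.07 ± 0.38 (SD, n = 5) relative to the pool in intact males and at -4.88 ± 0.66 (SD, n = 5) in intact females. Kdm5d, a Y-linked histone demethylase, lay at 0.93 ± 0.45 (SD, n = 5) and -1.94 ± 0.89 (SD, n = 5). All 20 females lay below all 20 males for both genes, so the values matched the sex in every animal's label. The X-linked partner Eif2s3x was higher in 17 of 20 females than in any male. The estrogen receptor gene Esr1 differed between intact females and males by 0.02, with a limma adjusted p of 0.95, and the growth hormone receptor gene Ghr by -0.48, with an adjusted p of 0.223.

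**Figure D1:**
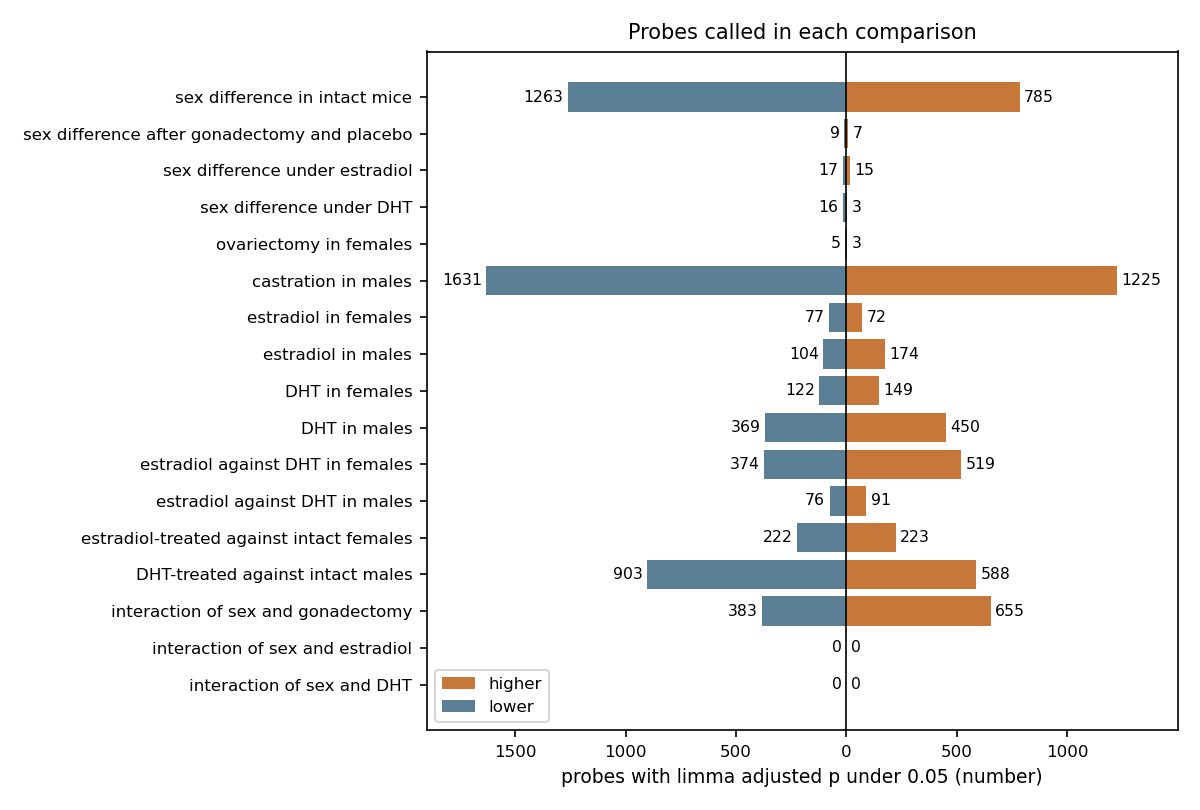
Number of probes with a limma adjusted p under 0.05 in each of 17 comparisons of 23574 probes, with bars to the right for higher and to the left for lower in the group named first (females for sex differences, treated or gonadectomized animals for the others). The castration bar holds 2856 probes and the ovariectomy bar 8.

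Intact females had 70.6-fold more Cyp2b13 and 43.2-fold more Cyp2b9 transcript, both cytochrome P450 genes, at differences of 6.14 ± 0.72 and 5.43 ± 0.61. The organic anion transporter gene Slc22a26 (5.81 ± 0.56), the plasma glycoprotein gene A1bg (5.41 ± 0.77), the sulfotransferase genes Sult3a1 (5.08 ± 0.64) and Sult2a1 (4.28 ± 0.61), and the hydroxy acid oxidase gene Hao2 (4.75 ± 0.61) were also higher in females. Males had 46.8-fold more Hsd3b5, a ketosteroid reductase, at a female minus male difference of -5.55 ± 0.73, and 18.8-fold more Cyp7b1, an oxysterol hydroxylase, at -4.23 ± 0.68. The acetyltransferase gene Nat8 (-4.64), Cyp2d9 (-3.83), the fatty acid elongase gene Elovl3 (-3.73), Cyp4a12a (-3.24), the asparagine synthetase gene Asns (-3.00) and the pseudogene Serpina4-ps1 (-2.82) were higher in males too. Of the 20 genes named by the rule here, each with an adjusted p of at most 0.00582, the rest were Slc22a27, Cyp17a1 and Cyp2c40 in females and the 2 Y-linked genes in males. A total of 2048 probes passed, 785 higher in females and 1263 higher in males, which is 8.69% of those tested. Of these, 460 differed at least 1.5-fold and 179 at least 2-fold.

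Other probes of several of these genes read much smaller differences. Further probes gave 0.71 for Cyp2b13, 0.24 for Cyp2b9, 0.86 for Sult3a1, -0.01 for Cyp2c40 and -0.12 for Hsd3b5, so the sizes above belong to the probe of largest spread. Genes of these families are also close in sequence, and the arrays' separation of them was not tested.

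Among lists of genes, known female-biased liver genes were higher in females: 14 of 24 measured genes rose and 1 fell, or 18 and 1 adjusted over the list alone, with a median of 0.94. The limma camera test gave an adjusted p of 2e-15, and 0.0166 with an estimated correlation. Of 17 known male-biased genes, 13 were lower in females and 0 higher, over all genes and adjusted over the list alone, with a median of -1.55 and an adjusted p of 6.66e-20, and 0.00276 with an estimated correlation. Selenbp2 (-2.25), a selenium binding protein gene, and Cyp4a12b (-0.93) were among them. In steroid hormone metabolism, 2 of 16 genes were higher in females and 6 lower, in both counts, with Cyp17a1, a steroid hydroxylase and lyase, at 2.91 ± 0.44 on the female side, for an adjusted p of 0.0284 that was 0.0565 with an estimated correlation. Complement and coagulation genes were lower in females, with 5 of 25 lower and 1 higher (7 and 2 adjusted over the list alone), among them the terminal complement genes C9 (-2.0), C8a (-1.02) and C6 (-0.32), and C2 (-0.56), while the coagulation factor gene F7 was higher (0.37). That list had an adjusted p of 0.0284, and 0.653 with an estimated correlation.

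Smaller shifts in intact animals passed only with the preset correlation, each at an adjusted p of 0.0284. Fatty acid oxidation genes were higher in females in 3 of 20 cases (4 adjusted over the list alone), led by Pdk4, a kinase that limits glucose oxidation, at 1.69, with an adjusted p = 0.694 with an estimated correlation. Cholesterol synthesis genes were lower in 2 of 16 cases (5 adjusted over the list alone), with Insig1 at -1.0 and Fdps at -0.76 (other probes at -0.60, -0.21 and 0.01), and an adjusted p = 0.702 with an estimated correlation. Of 14 genes of the unfolded protein response, Asns and Calr (-0.65) were lower (2 adjusted over the list alone), with an adjusted p = 0.562 with an estimated correlation. T and B cell markers were higher in females in 2 of 13 cases in both counts, Cd3d at 0.26 and Cd2 at 0.49, with an adjusted p = 0.562 with an estimated correlation. The endothelial marker Tek, 1 of 10 in both counts, was higher by 0.21, with an adjusted p = 0.192 with an estimated correlation.

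Against intact males, castrated males with placebo had 65.4-fold more Cyp2b13 (6.03 ± 0.72), 56.2-fold more Slc22a26 (5.81 ± 0.56) and 41.4-fold more Cyp2b9 (5.37 ± 0.61). Hao2 (4.32), A1bg (3.63), Sult3a1 (3.41), Rgs16 (3.32), a regulator of G protein signalling, Slc22a27 (3.16), Cyp2c40 (2.56) and Pde6c (2.31) also rose. Hsd3b5 fell by 5.70 ± 0.73, or 52-fold, and Elovl3 (-4.42), Serpina4-ps1 (-4.37), Cyp7b1 (-3.85), the monooxygenase gene Moxd1 (-3.59), Cyp4a12a (-3.34), Nat8 (-2.86), Bmf (-2.80), a gene of apoptosis, Asns (-2.69) and Cd248 (-2.55) fell too. Moxd1 was at -4.37 without animal 11 and -2.88 without animal 12. Other probes read 0.80 for Cyp2b13, 0.34 for Cyp2b9, 0.23 for Sult3a1, 0.06 for Cyp2c40, 0.15 for Pde6c and -0.10 for Hsd3b5. A total of 2856 probes passed, 1225 higher and 1631 lower, 12.1% of those tested, with 560 at least 1.5-fold and 204 at least 2-fold. The count was 1728 with the clock index as a covariate, 1802 with quantile normalization and 7762 with array weights.

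Of 24 known female-biased genes, 16 rose after castration and 1 fell (17 and 1 adjusted over the list alone), while Sult2a1 differed by 0.29 (another probe by -0.32) with an adjusted p of 0.792. The list had an adjusted p of 3.49e-10 in limma's camera test, and an adjusted p = 0.0697 with an estimated correlation. Of 17 known male-biased genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), at 3.08e-19, and 0.00345 with an estimated correlation. Steroid hormone metabolism genes fell in 6 of 16 cases and rose in 1 (9 and 3 adjusted over the list alone), with Ugt2b5, a glucuronosyltransferase gene, at -1.70 (other probes at -0.03 and -0.57) and Akr1c6 at -0.78, for an adjusted p of 0.0062, and 0.017 with an estimated correlation. Fatty acid synthesis genes rose in 4 of 18 cases (6 adjusted over the list alone), namely Acaca (0.70, with other probes at 0.12 and 0.17), Fasn (0.77), Fads1 (0.50) and Pnpla3 (0.37), at 0.0062, with an adjusted p = 0.619 with an estimated correlation. Complement genes fell in 4 of 25 cases and rose in 2 (5 and 2 adjusted over the list alone), with C9 at -2.30 and Mbl1 at -0.51 lower and the coagulation factor genes F7 (0.45) and F10 (0.29) higher, at 0.0485, with an adjusted p = 0.708 with an estimated correlation. The T and B cell markers Cd2 (0.62) and Cd3d (0.24), 2 of 13 (4 adjusted over the list alone), rose at 0.0162, with an adjusted p = 0.601 with an estimated correlation. The clock index differed by 0.56 between castrated and intact males, with an exact p of 0.0238 and an adjusted p of 0.0536 over 9 comparisons. Ghr differed by -0.61 with an adjusted p of 0.0822 in limma, and Esr1 by -0.04 with an adjusted p of 0.864.

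Ovariectomy moved few probes. Cdkn1a, a cyclin-dependent kinase inhibitor, fell by 1.72 ± 0.25, or 3.3-fold, and Emb, which encodes embigin, fell by 0.81 ± 0.12. Nr1d1, a repressor in the circadian clock, rose by 1.16 ± 0.22, with Sp5 (0.82) and Tbc1d10a (0.77), while Btg1 fell by 0.56. A total of 8 probes passed, 3 higher and 5 lower, with 2 without each of animals 1, 2, 4, 16, 17 and 19, 3 without animal 3, 5 without 18 and 23 without 20. Only Cdkn1a and Emb of the 6 named genes kept their call without each animal in turn, and limma called 0 probes with the clock index as a covariate, with 687 at an unadjusted p under 0.05. That index was higher after ovariectomy by 0.89, with an exact p of 0.00794 and an adjusted p of 0.0536 over 9 comparisons. It ran from -0.914 to -0.587 in intact and from -0.371 to 0.352 in ovariectomized females, without overlap, and Nr1d1 is part of it. The fit with the index therefore cannot tell a clock effect from an effect of ovariectomy.

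Several metabolic lists shifted after ovariectomy with the preset correlation in limma's camera test, and none with an estimated one. Cholesterol synthesis genes had a median of 0.24, with 0 of 16 higher (3 adjusted over the list alone), Insig1 at 1.07, and an adjusted p of 5.49e-08 that was an adjusted p = 0.306 with an estimated correlation. Fatty acid synthesis genes had a median of 0.20, with 0 of 18 called in both counts, at 3.34e-06, and an adjusted p = 0.306 with an estimated correlation. In fatty acid oxidation 1 of 20 genes, Pdk4 at -1.32, was lower (3 adjusted over the list alone, Angptl4 at -0.75 among them), at 0.000628, and an adjusted p = 0.509 with an estimated correlation. Foreign compound metabolism genes, at a median of 0.16 with 0 of 21 called, and hepatocyte genes, at -0.14 with 0 of 8 called, each had an adjusted p of 0.0418, and adjusted p = 0.686 and adjusted p = 0.489 with an estimated correlation. The lists of known sex-biased genes did not pass.

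The effect of gonadectomy differed between the sexes, by a test of the difference itself. The female minus the male change was 5.74 ± 1.03 for Hsd3b5, 4.40 ± 0.58 for Elovl3, 3.86 for Cyp7b1, 3.65 for Moxd1 and 3.32 for Cyp4a12a. It was -5.84 ± 0.79 for Slc22a26, -5.69 ± 1.02 for Cyp2b13, -5.23 ± 0.86 for Cyp2b9, -3.84 for Sult3a1 and -3.58 for Hao2. Moxd1 was at 4.43 without animal 11 and 2.94 without animal 12. Other probes read 0.19 for Hsd3b5, -0.50 for Cyp2b13, -0.30 for Cyp2b9 and -0.23 for Sult3a1. A total of 1038 probes passed for this interaction, 655 positive and 383 negative. Known male-biased genes were positive in 12 of 17 cases (13 adjusted over the list alone), with an adjusted p of 3.84e-17 in limma's camera test, and 0.00705 with an estimated correlation. Known female-biased genes were negative in 9 of 24 cases and positive in 1 (13 and 1 adjusted over the list alone), at 1.69e-09, with an adjusted p = 0.0903 with an estimated correlation. Steroid hormone metabolism genes were positive in 6 of 16 cases and negative in 1, Cyp17a1 at -2.37, in both counts, at 0.0203, and an adjusted p = 0.0551 with an estimated correlation. Cholesterol synthesis genes, at a median of 0.24 with 0 of 16 called, had 0.0203, and an adjusted p = 0.796 with an estimated correlation, and T and B cell markers, at -0.29 with 0 of 13 called, had 0.00892, and an adjusted p = 0.413 with an estimated correlation.

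After gonadectomy and placebo the sexes differed in few genes beyond those of the Y chromosome. Sult2a1, which sulfates steroids and bile acids, remained 13.7-fold higher in females, at 3.77 ± 0.61, and Dct, a gene of melanin synthesis, was 3.74-fold higher at 1.90 ± 0.36. Higher in males were Eif2s3y (-5.44), Kdm5d (-2.31), the glycine cleavage gene Gcsh (-1.10), the Y-linked Ssty1 (-1.05) and Impg1 (-0.44). A total of 16 probes passed, 7 higher in females and 9 in males, and Dct lost its call without any of 5 single animals. Eif2s3x differed by 0.39 with an adjusted p of 0.456, and fatty acid oxidation genes, with 0 of 20 called and a median of 0.09, passed in limma's camera test at 0.0497, with an adjusted p = 0.84 with an estimated correlation.

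Across 458 probes of the intact sex difference, the slope of the placebo sex difference on the intact one was 0.161, with a jackknife SE of 0.031 and a range from 0.146 to 0.175 on leaving out each animal. It was 0.244 with quantile normalization. A total of 10 probes passed in both comparisons in the same direction and 0 in opposite ones, and 41.9% had the same sign in both. Probes are not independent replicates, and the comparisons share no animal.

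**Figure D2:**
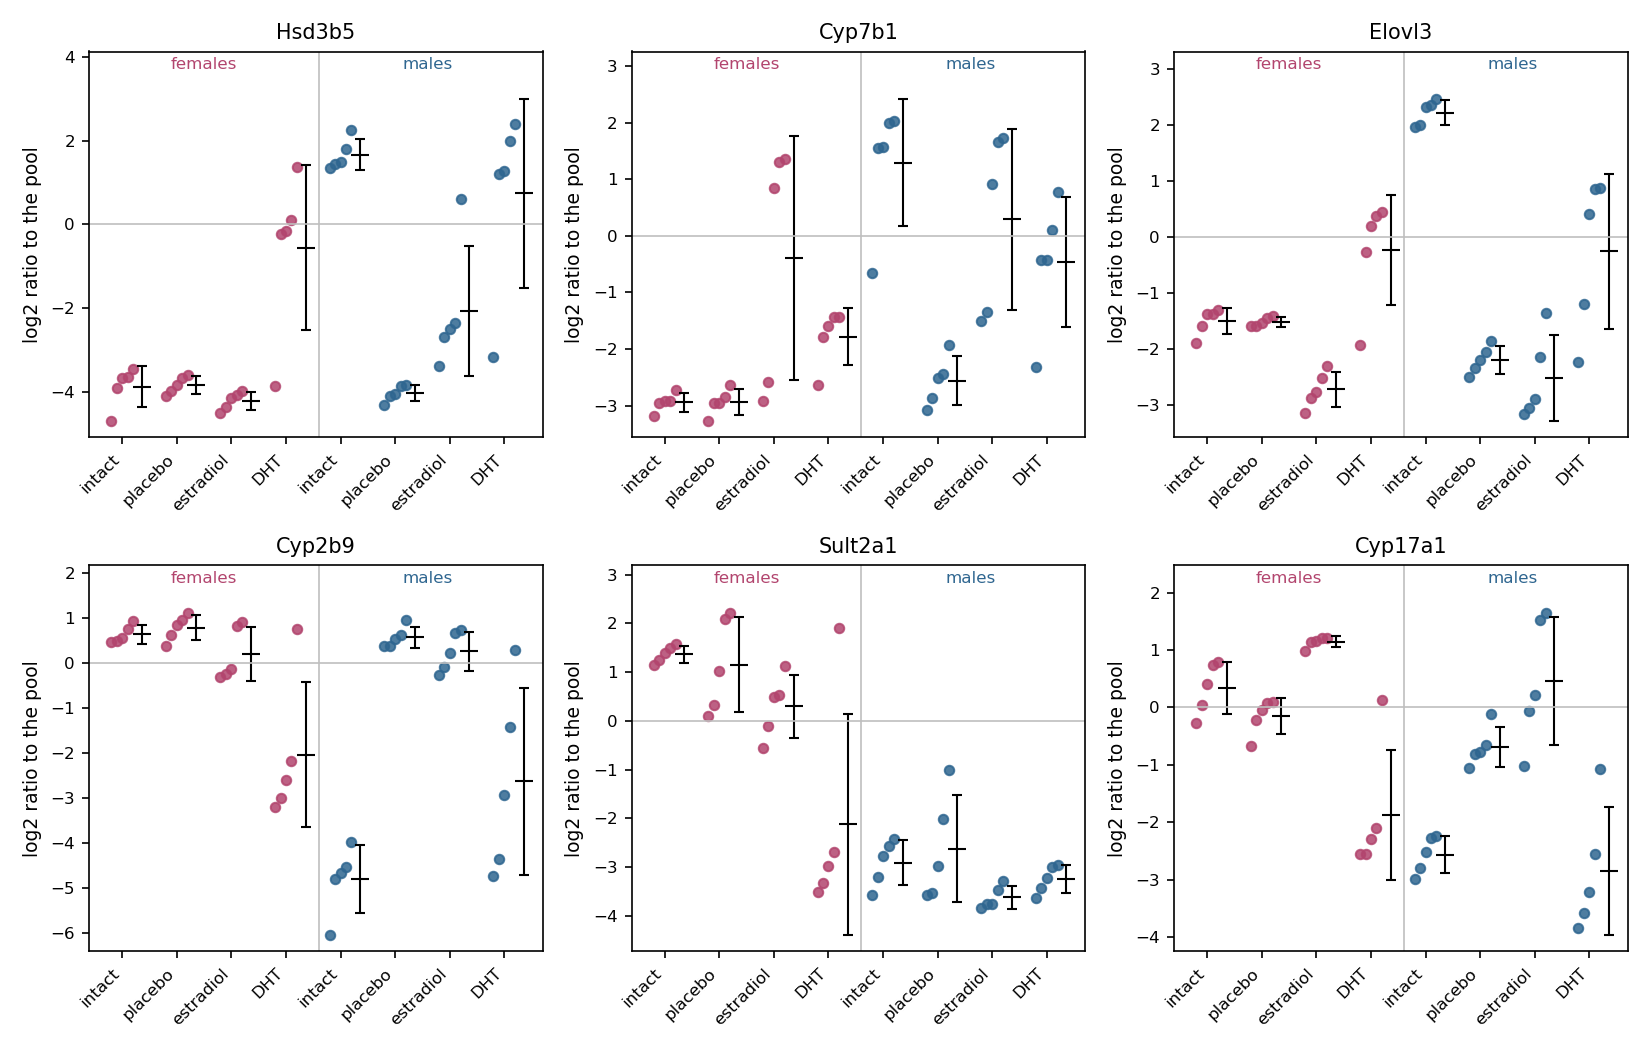
Log2 ratio to the pool of 40 livers in each liver for 6 genes, with points for 5 animals per group in order of value and a black dash and bar for mean ± SD. Hsd3b5 lay near 1.66 in intact males and near -4.04 in castrated males with placebo. Under DHT, animal 53 among the females, at -3.87, and animal 61 among the males, at -3.19, lay far below the others.

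Estradiol in ovariectomized females raised Miox, the first enzyme of inositol breakdown, by 1.68 ± 0.29, or 3.21-fold, and Rgp1 by 1.11 ± 0.18. It lowered the mitochondrial glycerol phosphate dehydrogenase gene Gpd2 by 1.08 ± 0.16 (log2 -1.08), the carbonic anhydrase gene Car1 (-1.33 ± 0.21), the retinaldehyde dehydrogenase gene Aldh1a1 (-1.06 ± 0.18) and the keratin gene Krt23 (-1.35 ± 0.25). These 6 genes kept an adjusted p under 0.05 in limma without each animal in turn. The other 14 named genes passed over all animals but not without every single one: the B cell chemokine gene Cxcl13 (2.09), Spon1 (2.04), Mmd2 (2.00), Dntt (1.87), the trehalase gene Treh (1.32), Pla2g7 (1.14), Fkbp5 (1.01) and Serpina3f (1.00) rose, and G0s2, an inhibitor of fat breakdown (-1.83), Lamb3 (-1.72), the corticosteroid-binding globulin gene Serpina6 (-1.48), Car3 (-1.46), Raet1d (-0.98) and Paqr7 (-0.96) fell. A total of 149 probes passed, 72 higher and 77 lower. The count ran from 22 without animal 36 to 902 without animal 34 and moved over 1.5 times on leaving out any 1 of the 10 animals, and it was 55 with only these groups in the fit and 1092 with array weights. It was 418 without animal 33 and 23 without each of 35 and 37. Relative to the pool, Cyp7b1 lay at -2.57 and -2.92 in animals 33 and 34 and at 1.35, 0.84 and 1.31 in animals 35, 36 and 37. Cyp17a1 showed no such split, at 0.98 to 1.22 in all 5.

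Lists of lipid genes were lower under estradiol in females with the preset correlation in limma's camera test. Fatty acid synthesis genes fell in 2 of 18 cases, Fads1 (-0.67) and Me1 (-0.59), and adjusted over the list alone 10 were lower and 2 higher, at an adjusted p of 1.65e-06, and an adjusted p = 0.176 with an estimated correlation. Fatty acid oxidation genes fell in 3 of 20 cases (7 adjusted over the list alone), namely Cpt2 (-0.56), the peroxisome gene Pex11a (-0.84) and the transcription factor gene Ppara (-0.67), at 1.02e-05, and an adjusted p = 0.187 with an estimated correlation. Genes of the unfolded protein response had a median of 0.27 with 0 of 14 called in both counts, at 0.000159, and an adjusted p = 0.176 with an estimated correlation. Respiratory chain genes had a median of -0.17 with 0 of 10 called in both counts, at 0.00385, and an adjusted p = 0.341 with an estimated correlation. Kupffer cell and macrophage markers had a median of 0.72, with 0 of 14 called over all genes and 13 higher adjusted over the list alone, at 1.65e-11, and an adjusted p = 0.176 with an estimated correlation. Red cell genes had a median of 0.33 with 0 of 8 called in both counts, at 0.0221, and an adjusted p = 0.187 with an estimated correlation. The macrophage score was 0.51 ± 0.77 (SD, n = 5) under estradiol and -0.24 ± 0.21 (SD, n = 5) under placebo, with an exact p of 0.0794 and an adjusted p of 0.357 over 9 comparisons.

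In castrated males, estradiol raised Egfr, the epidermal growth factor receptor gene, by 1.71 ± 0.29, or 3.28-fold, and the sulfotransferase gene Sult5a1 by 1.21 ± 0.19, both known male-biased genes, and Serpina3f by 1.15 ± 0.24. It lowered Pde6c (-1.71 ± 0.31), Gpd2 (-0.96 ± 0.16), Crip2 (-0.80) and Rbmx (-0.75), though other probes read -0.08 for Pde6c, -0.05 for Crip2 and 0.01 for Rbmx. Cyp7b1 was higher by 2.85 ± 0.68 with an adjusted p of 0.0289 in limma, which ran from 0.0036 to 0.0974 over the alternatives and rose above 0.05 without each of animals 24, 25, 26, 43, 44 and 46. Relative to the pool it lay at 1.72, 1.65 and 0.92 in the estradiol-treated males 43, 44 and 46 and at -1.50 and -1.34 in 41 and 45. Their macrophage scores were 0.79, 0.15 and -0.15, and -0.45 and -0.20, in the same order. Such a division of the animals was not tested. Serpina4-ps1 (3.06), Mmd2 (1.86), Dntt (1.60), Dct (1.48), Treh (1.33) and Upp2 (1.19, with another probe at 0.05) rose, and Gsta2 (-1.32), H1f2 (-1.02), Sh2b3 (-0.89), Gsta4 (-0.69), Epha2 (-0.68) and Zfp503 (-0.68) fell, and each of these lost its call without at least 1 animal. A total of 278 probes passed, 174 higher and 104 lower. The count was 69 without animal 24, 144 without animal 25, 165 without animal 26, 179 without animal 45 and 84 without animal 46, and it was 37 with only these groups in the fit and 753 with array weights.

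Steroid hormone metabolism genes rose under estradiol in castrated males in 2 of 16 cases (7 adjusted over the list alone), Cyp7b1 and Hsd3b2 (0.98), with an adjusted p of 0.00124 in limma's camera test, and 0.00787 with an estimated correlation. Known male-biased genes rose in 3 of 17 cases (6 adjusted over the list alone) at 0.00072, and an adjusted p = 0.39 with an estimated correlation. The fatty acid synthesis gene Acaca fell (-0.57, with other probes at -0.19 and -0.13), 1 of 18 (adjusted over the list alone 7 lower and 1 higher), at 0.0101, and an adjusted p = 0.541 with an estimated correlation. Fatty acid oxidation genes had a median of -0.22 with 0 of 20 called (5 lower adjusted over the list alone) at 0.00072, and an adjusted p = 0.39 with an estimated correlation. The unfolded protein response had a median of 0.22 with 0 of 14 called (1 higher adjusted over the list alone) at 0.00211, and an adjusted p = 0.39 with an estimated correlation. Respiratory chain genes had a median of -0.18 with 0 of 10 called at 0.0347, and an adjusted p = 0.541 with an estimated correlation. Macrophage markers had a median of 0.24 with 0 of 14 called at 0.0161, and an adjusted p = 0.705 with an estimated correlation. The endothelial marker Tek fell (-0.24), 1 of 10 (2 adjusted over the list alone), at 0.0414, and an adjusted p = 0.39 with an estimated correlation.

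The estradiol responses of both sexes overlapped. Among the 149 and 278 probes called, 20 were higher in both and 15 lower in both, where independent lists would share 0.531 and 0.34, and 0 moved in opposite directions. The correlation of the responses across probes was 0.533, and probes are not independent replicates. The arrays of these comparisons are separate, and Gpd2, Mmd2, Dntt, Treh and Serpina3f were named in both. For the difference in response between the sexes limma called 0 probes, with 973 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0844, and 3 with array weights. As lists, known male-biased genes (median -0.37, 0 of 17 called) and macrophage markers (0.45, 0 of 14 called) passed for that difference at an adjusted p of 0.00279 in limma's camera test, each with an adjusted p = 0.553 with an estimated correlation. Steroid hormone metabolism genes (-0.14, 0 of 16 called and 1 lower adjusted over the list alone) had 0.0153, and an adjusted p = 0.0716 with an estimated correlation, and T and B cell markers (0.17, 0 of 13 called) had 0.00463, and an adjusted p = 0.553 with an estimated correlation.

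DHT in ovariectomized females lowered A1bg by 4.75 ± 0.77, or 27-fold, and the DNA repair gene Rad51b (-1.50 ± 0.28), Cables1 (-1.22), P2ry14 (-1.01), the monocarboxylate transporter gene Slc16a6 (-0.87) and Denn2b (-0.87). Without animal 53 the difference of A1bg was -5.70, or 51.9-fold. It raised the uridine phosphorylase gene Upp2 (1.52 ± 0.30, with another probe at 0.09), Serpina3f (1.35 ± 0.24) and the alcohol dehydrogenase gene Adh4 (1.08 ± 0.22). These 9 kept an adjusted p under 0.05 in limma without each animal in turn, and the other 11 did not: Omd (1.66), Treh (1.4), C9 (1.38), Clec2h (1.34), the organic anion transporter gene Slco1a1 (1.22), Ces3b (1.01) and the heme synthesis gene Alas1 (0.99) rose, and Ly6d (-1.34), Pdk4 (-1.10), Defb1 (-1.06) and Clpx (-0.97) fell. Hsd3b5 (3.29), Cyp2b13 (-3.86) and Cyp2b9 (-2.82) passed too, but the rule did not name them because the groups overlapped. Without animal 53 they were at 4.12 (17.4-fold), -4.85 and -3.52. Other probes of these genes are not given for this contrast. A total of 271 probes passed, 149 higher and 122 lower. The count was 443 without animal 53 and from 89 to 173 without each of 8 others, animals 16, 18, 19, 20, 50, 51, 52 and 54. It was 757 with quantile normalization and 545 with only these groups in the fit.

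Known female-biased genes fell under DHT in females in 8 of 24 cases and adjusted over the list alone in 12, with 1 higher, among them Hao2 (-4.17), Sult3a1 (-3.60, with another probe at -0.74) and Sult2a1 (-3.27). The adjusted p in limma's camera test was 1.53e-09, and an adjusted p = 0.119 with an estimated correlation. Known male-biased genes rose in 5 of 17 cases (8 adjusted over the list alone), with Cyp2d9 (2.61), Cyp4a12a (1.68) and Egfr (1.44), at 1.33e-08, and an adjusted p = 0.119 with an estimated correlation. Without animal 53 the differences were -5.20 for Hao2, -4.68 for Sult3a1, -4.28 for Sult2a1 and 3.34 for Cyp2d9. Known estrogen-responsive genes fell in 2 of 16 cases (4 adjusted over the list alone), Cyp17a1 (-1.72) and the cyclin gene Ccnd1 (-0.79), at 0.0151, and an adjusted p = 0.187 with an estimated correlation. Of 20 fatty acid oxidation genes, Pdk4 alone fell in both counts, at 0.045, and an adjusted p = 0.542 with an estimated correlation. The clock index was higher by 0.35, with an exact p of 0.0238 and an adjusted p of 0.0536 over 9 comparisons.

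In castrated males DHT raised Hsd3b5 by 4.78 ± 0.73, or 27.4-fold, from -4.04 ± 0.19 (SD, n = 5) to 0.74 ± 2.25 (SD, n = 5). Serpina4-ps1 (3.48), Egfr (2.00 ± 0.29), Alas1 (1.58), the steroid dehydrogenase gene Hsd3b2 (1.51), Bmf (1.51), Upp2 (1.46), and the carboxylesterase genes Ces3a (1.36) and Ces3b (1.35) rose, as did Cyp2d9 (1.52), which lost its call without any of 7 single animals. Cyp2b13 (-3.86 ± 0.72), Hao2 (-3.50), Slc22a26 (-3.36), Cyp2b9 (-3.20), Slc22a27 (-2.55), Cyp17a1 (-2.17), Rad51b (-1.89), Cyp2c40 (-1.79), Celsr1 (-1.49) and the clock activator gene Arntl (-1.38) fell. Without animal 61 the differences were 5.76 (54-fold) for Hsd3b5, 4.12 for Serpina4-ps1, -4.74 for Cyp2b13, -4.03 for Slc22a26 and -3.93 for Cyp2b9. Other probes read 0.02 for Hsd3b5, -0.06 for Upp2, -0.68 for Cyp2b13, -0.28 for Cyp2b9 and 0.14 for Cyp2c40. A total of 819 probes passed, 450 higher and 369 lower, with 335 without animal 62, 338 without 59, 425 without 27, 491 without 24 and 500 without 60, and 260 with only these groups in the fit. The count was 3801 with array weights and 1271 without the arrays of wide residual spread. The clock index was higher by 0.44, with an exact p of 0.0238 and an adjusted p of 0.0536 over 9 comparisons.

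Known male-biased genes rose under DHT in castrated males in 10 of 17 cases (11 adjusted over the list alone), with Cyp4a12a at 2.28 and Selenbp2 at 1.11. The adjusted p in limma's camera test was 1.26e-14, and 0.0174 with an estimated correlation. Known female-biased genes fell in 8 of 24 cases (11 adjusted over the list alone) at 4.89e-10, and an adjusted p = 0.0736 with an estimated correlation. Steroid hormone metabolism genes rose in 4 of 16 cases and fell in 1 (7 and 2 adjusted over the list alone), at 0.0175, and 0.0314 with an estimated correlation. The DHT responses of both sexes shared 94 higher probes, where independent lists would share 2.84, and 42 lower ones against 1.91, with 0 in opposite directions and a correlation across probes of 0.502. For the difference in response between the sexes limma called 0 probes, with 1790 at an unadjusted p under 0.05 and a smallest adjusted p of 0.222, and 762 with array weights. With the preset correlation, foreign compound metabolism genes passed for that difference, with a median of 0.40, 0 of 21 called and an adjusted p of 0.0242, and an adjusted p = 0.961 with an estimated correlation.

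The score of the intact sex difference summarised these changes per liver. It was 0.83 ± 0.07 (SD, n = 5) in intact females, 0.74 ± 0.13 in ovariectomized females with placebo, 0.60 ± 0.17 with estradiol and -0.53 ± 0.64 with DHT. In males it was -1.72 ± 0.27 (SD, n = 5) intact, 0.48 ± 0.06 after castration with placebo, -0.10 ± 0.18 with estradiol and -0.81 ± 0.62 with DHT. Against placebo, DHT lowered the score in females by a difference of -1.27 ± 0.29 (SE), with an exact p of 0.0159 and an adjusted p of 0.0199 over 5 comparisons, and in males by -1.29 ± 0.28, with an exact p of 0.00794 and an adjusted p of 0.0198. Estradiol lowered it in males by -0.57 ± 0.08, with an exact p of 0.00794 and an adjusted p of 0.0198. In females the estradiol difference was -0.14 ± 0.10, with an exact p of 0.175 and an adjusted p of 0.175. Under estradiol, the females 33 and 34 lay at 0.81 and 0.76, and 35, 36 and 37 at 0.51, 0.48 and 0.43. Ovariectomized and castrated animals with placebo differed by 0.26 ± 0.07, with an exact p of 0.0159 and an adjusted p of 0.0199, of which the female-biased probes gave 0.266 and the male-biased ones 0.002. With a 1.2-fold threshold for its probes that difference was 0.06 with an exact p of 0.159. Of the 299 male-biased probes, 150 rose and 0 fell under DHT in castrates, 84 and 0 under DHT in ovariectomized females, and 27 and 0 under estradiol in castrates. Of the 161 female-biased probes, 52 fell under DHT in males and 46 in females, and 0 rose.

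**Figure D3:**
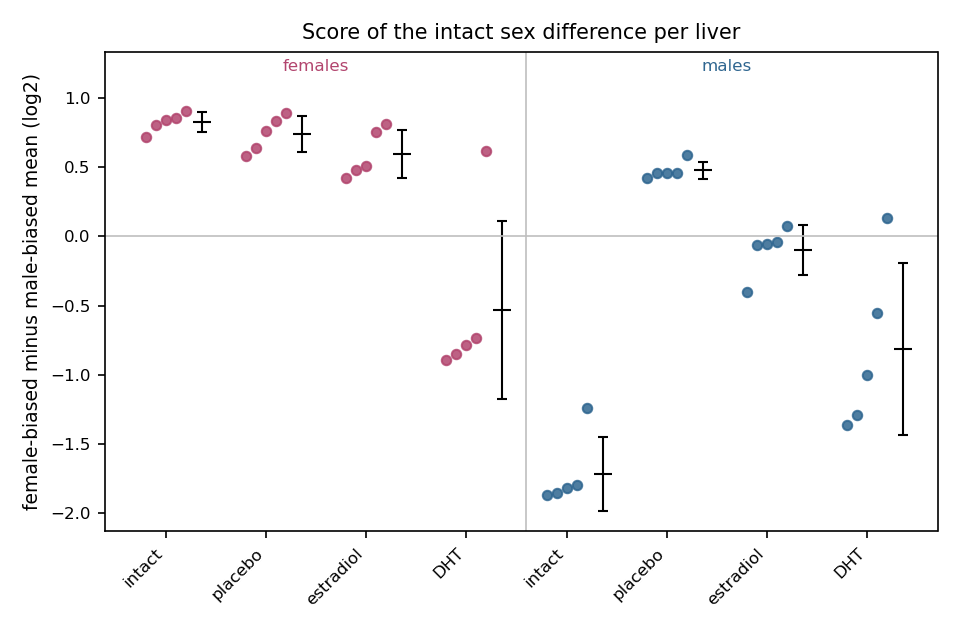
Score of the intact sex difference, the mean log2 ratio of female-biased minus male-biased probes, in each of 40 livers, with points for 5 animals per group in order of value and a black dash and bar for mean ± SD. The intact groups lie at 0.83 and -1.72 and define the score, and the castrated males with placebo lie at 0.48.

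Estradiol has an aromatic A ring with a phenol hydroxyl, DHT has a saturated A ring with a ketone, and the pellets held 0.5 mg and 5 mg. In females, livers under estradiol held 8.09-fold more Cyp17a1 than those under DHT (3.02 ± 0.44) and 5.12-fold more Cxcl13 (2.36 ± 0.43), with Corin (2.27), Mmd2 (2.27) and Cyp2c40 (1.97) higher as well. Hsd3b5 was 12.7-fold higher under DHT, at -3.66 ± 0.73, with Elovl3 (-2.49), Nat8 (-2.02), Cyp4a12a (-1.77) and Car1 (-1.74). Without animal 53 Hsd3b5 was at -4.49, or 22.5-fold. Genes that passed with overlapping groups were not named, among them Sult3a1 (4.465), A1bg (3.64), Cyp2b13 (2.91) and Hao2 (2.65), all higher under estradiol. Without animal 53 these were at 5.55, 4.59, 3.90 and 3.68. Other probes of Sult3a1 and Cyp2b13 are not given for this contrast. Other probes read 1.23, 0.47 and -0.09 for Cyp2c40 and -0.04 for Hsd3b5. A total of 893 probes passed, 519 higher under estradiol and 374 under DHT. The count was 281 without animal 36, 460 without 37, 538 without 35, 1523 without 34, 495 without 54, 560 without 52 and 562 without 50, and it was 184 with the clock index as a covariate. That index ran from -0.352 to 0.346 under estradiol and from 0.32 to 0.725 under DHT. With so little overlap, the fit can hardly tell a clock effect from a difference between these groups.

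Kupffer cell and macrophage markers were higher under estradiol than under DHT in females in 11 of 14 cases (13 adjusted over the list alone), led by Csf1r (1.34), Clec4f (0.86), C1qc (1.25) and C1qa (1.17). The list had an adjusted p of 2.27e-14 in limma's camera test, and an adjusted p = 0.0787 with an estimated correlation, and limma called 0 markers without animals 35 and 36, with 7 at an unadjusted p under 0.05. Known female-biased genes were higher under estradiol in 10 of 24 cases (13 adjusted over the list alone), at 3.9e-10, and an adjusted p = 0.0787 with an estimated correlation. Known male-biased genes were lower in 6 of 17 (8 adjusted over the list alone), at 3.69e-05, and an adjusted p = 0.268 with an estimated correlation. Known estrogen-responsive genes were higher in 4 of 16 (5 adjusted over the list alone), namely Cyp17a1, the cytokine signalling inhibitor gene Socs2 (1.70), Ccnd1 (0.72) and Tff3 (1.4), at 3.69e-05, and an adjusted p = 0.0536 with an estimated correlation. Foreign compound genes were lower in 4 of 21 cases (6 lower and 1 higher adjusted over the list alone), Aldh1a1 (-1.12) first, at 0.0298, and an adjusted p = 0.409 with an estimated correlation. Acute phase genes, with Itih3 (0.78) and Lbp (0.42) higher among 20 (4 higher and 1 lower adjusted over the list alone), had an adjusted p of 0.0286, and an adjusted p = 0.491 with an estimated correlation. Cell cycle genes, with Ccnd1 and Plk1 (0.43) higher among 22 (4 adjusted over the list alone), had 0.0298, and an adjusted p = 0.312 with an estimated correlation. Among 18 fatty acid synthesis genes Elovl6 (-0.89) and Me1 (-0.67) were lower and Scd2 (0.55) higher (3 and 1 adjusted over the list alone), at 0.00199, and an adjusted p = 0.317 with an estimated correlation. The respiratory chain genes Ndufa2 (-0.23) and Cox7a2 (-0.37) were lower among 10 (4 adjusted over the list alone), at 0.00266, and the B cell gene Cd79b (0.66) was higher among 13 (3 adjusted over the list alone), at 0.00652, each with an adjusted p = 0.309 with an estimated correlation.

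**Figure D4:**
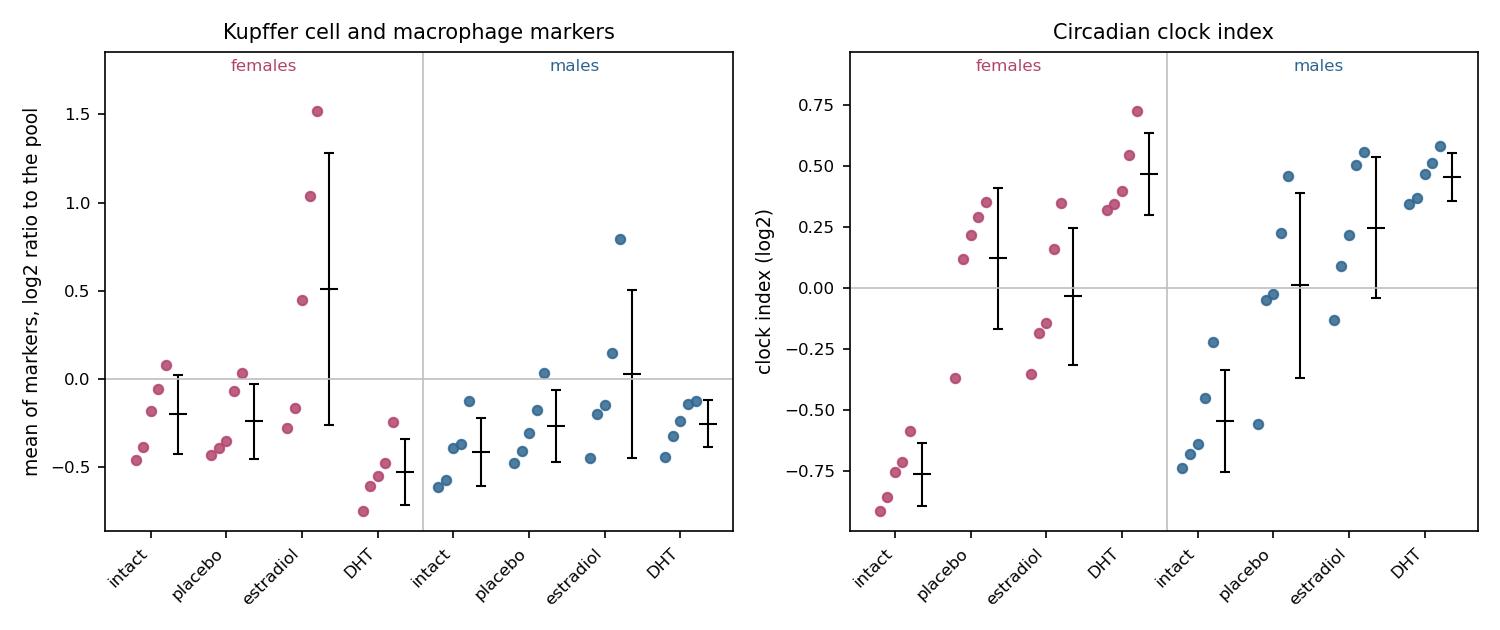
Mean log2 ratio to the pool of 14 Kupffer cell and macrophage markers (left) and clock index in log2 units (right) in each of 40 livers, with points for 5 animals per group in order of value and a black dash and bar for mean ± SD. The estradiol-treated females range from -0.28 to 1.52 on the left, and intact females and males lie at -0.77 and -0.55 on the right.

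In castrated males, estradiol gave 18-fold more Sult3a1 than DHT (4.17 ± 0.64, with another probe at 0.52) and 9.94-fold more Cyp17a1 (3.31 ± 0.44), and Slc22a26 (3.07), Mmd2 (2.42) and Corin (2.29) were higher too. Higher under DHT were Fbf1 (-1.18), Krt23 (-1.07), the bile acid hydroxylase gene Cyp8b1 (-1.04), Igfbp2 (-0.93) and Dnase1 (-0.84), and Corin, Krt23, Cyp8b1 and Igfbp2 lost their call without at least 1 animal. Slc22a26 was at 3.73 without animal 61. Known female-biased genes were higher under estradiol in 7 of 24 cases (11 adjusted over the list alone), at 1.52e-11 in limma's camera test, and an adjusted p = 0.114 with an estimated correlation. Known male-biased genes were lower in 2 of 17 (8 adjusted over the list alone), Elovl3 (-2.27) and Cyp4a12a (-1.84), at 7.29e-05, and an adjusted p = 0.38 with an estimated correlation. Of 20 acute phase genes, Lbp (0.59) and Apcs (1.37) were higher (4 adjusted over the list alone), at 0.0148, and an adjusted p = 0.765 with an estimated correlation. Of 16 estrogen-responsive genes Cyp17a1 alone was higher (4 higher and 1 lower adjusted over the list alone), at 0.0465, and an adjusted p = 0.415 with an estimated correlation. With 0 genes called, fatty acid oxidation (median -0.16 over 20 genes) had 0.0148, and an adjusted p = 0.597 with an estimated correlation, macrophage markers (0.18 over 14) had 0.0346, and an adjusted p = 0.83 with an estimated correlation, and stellate cell markers (0.28 over 10, with 4 higher and 1 lower adjusted over the list alone) had 0.021, and an adjusted p = 0.38 with an estimated correlation. A total of 167 probes passed, 91 higher and 76 lower under estradiol. The count was 48 without animal 59, 56 without 44, 64 without 60, 81 without 62, 102 without 43, 110 without 46 and 493 without 63, and 8 with only these groups in the fit.

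In estradiol-treated ovariectomized females Pdk4 was 4.01-fold lower than in intact females, at -2.0 ± 0.25, the glucose phosphatase gene G6pc 3.27-fold lower, at -1.71 ± 0.31, and Gadd45b (-1.50), Krt23 (-1.24) and Igfbp1 (-1.97) were lower, while Mmd2 (2.39), Cxcl13 (2.05), the sterol synthesis gene Sqle (1.99 ± 0.38), Spon1 (1.95) and Dntt (1.79) were higher. Cxcl13, Dntt, Igfbp1 and Spon1 lost their call without at least 1 animal. Fatty acid oxidation genes were lower in 6 of 20 cases (9 adjusted over the list alone), with Cpt2 (-0.71) and Angptl4 (-0.89), at 8.02e-12 in limma's camera test, and 0.0404 with an estimated correlation. Cholesterol synthesis genes were higher in 3 of 16 cases (9 adjusted over the list alone), Sqle, Fdft1 (1.05) and Insig1 (1.03), at 1.05e-06, and an adjusted p = 0.214 with an estimated correlation. Of 12 genes of glucose metabolism G6pc, Irs2 (-1.13) and Pygl (-0.34) were lower in both counts, at 0.0015, and an adjusted p = 0.214 with an estimated correlation. The macrophage marker Lyz2 was higher (0.63), 1 of 14 (9 adjusted over the list alone), at 4.61e-09, and an adjusted p = 0.214 with an estimated correlation. The unfolded protein response (median 0.15, 0 of 14 called) and the respiratory chain (-0.20, 0 of 10 called) each had 0.0015, and adjusted p = 0.214 and adjusted p = 0.254 with an estimated correlation. A total of 445 probes passed, 223 higher and 222 lower. The count was 1455 without animal 34, 251 without 5, 198 without 3, 172 without 2, 148 without 1, 114 without 35, 107 without 37 and 84 without 36, and 48 with only these groups in the fit. The clock index ran from -0.914 to -0.587 in intact and from -0.352 to 0.346 in estradiol-treated females, without overlap, a difference that was not tested. With the index as a covariate 646 probes passed, a fit that cannot tell a clock effect from a difference between these groups.

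In DHT-treated castrated males, the clock activator gene Arntl was lower than in intact males (-1.90 ± 0.26) and the clock repressor gene Per2 higher (1.77 ± 0.30), with Slc22a26 (2.45), Cxcl1 (1.98), Upp2 (1.82, with another probe at -0.11) and Serpina6 (1.71) higher and Elovl3 (-2.48), the sterol regulator gene Insig2 (-2.09), Clpx (-1.93) and the insulin receptor substrate gene Irs2 (-1.83, with another probe at -0.52) lower. Known male-biased genes were lower in 5 of 17 cases (9 adjusted over the list alone), with Moxd1 (-3.19) and Selenbp2 (-1.17), at 2.1e-05 in limma's camera test, and an adjusted p = 0.734 with an estimated correlation. Moxd1 was at -3.97 without animal 11 and -2.47 without animal 12, Slc22a26 at 1.79 without animal 61 and Cxcl1 at 1.36 without animal 63. A total of 1491 probes passed, 588 higher and 903 lower. The clock index was 0.45 ± 0.10 (SD, n = 5) in the treated and -0.55 ± 0.21 (SD, n = 5) in the intact males, without overlap, a difference that was not tested. The count was 10 with the clock index as a covariate, 372 with quantile normalization and 241 with only these groups in the fit, and it was 762 without animal 8, 861 without 61, 960 without 10, 981 without 12 and 2870 without 11. Without overlap of the index, the fit with that covariate cannot tell a clock effect from a difference between these groups.

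Under estradiol, Sult2a1 was 15.2-fold higher in females (3.92 ± 0.61), Gsdme (0.74) and Rasl11b (0.88) were higher, and Eif2s3y (-6.73), Kdm5d (-3.95), Cyp2d9 (-2.13), Nat8 (-1.91) and Gcsh (-1.24) were higher in males. Rasl11b and Cyp2d9 lost their call without at least 1 animal. A total of 32 probes passed, 15 higher and 17 lower in females, with 19 without animal 36 and 13 with only these groups in the fit. As lists under estradiol, known male-biased genes were lower in females in 1 of 17 cases (2 adjusted over the list alone) at 0.000319 in limma's camera test, and an adjusted p = 0.475 with an estimated correlation, and known female-biased genes higher in 1 of 24 (2 adjusted over the list alone) at 0.0341, and an adjusted p = 0.527 with an estimated correlation. Steroid hormone metabolism genes were lower in 2 of 16 (3 adjusted over the list alone), Cyp2d9 and Hsd3b2 (-1.15), at 0.0323, and an adjusted p = 0.106 with an estimated correlation. Complement genes (0 of 25 called, 4 lower adjusted over the list alone) had 0.0341, and an adjusted p = 0.527 with an estimated correlation, and macrophage markers (median 0.51, 0 of 14 called) had 7.73e-06, and an adjusted p = 0.475 with an estimated correlation.

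Under DHT, Eif2s3x (0.73 ± 0.12) and Celsr1 (0.94) were higher in females, and Eif2s3y (-6.18), Kdm5d (-2.53), Gcsh (-1.63), Ssty1 (-1.21) and Nsg2 (-0.54) in males, where Celsr1 and Nsg2 lost their call without at least 1 animal. A total of 19 probes passed, 3 higher and 16 lower in females, and 1310 passed with array weights. The 4 X-linked genes with a Y partner were higher in females as a list under DHT, 1 over all genes and 3 adjusted over the list alone, at 0.00172 in limma's camera test, and 0.0116 with an estimated correlation. Without any gene called, known male-biased genes (median -0.15 over 17) had 0.0143, and an adjusted p = 0.786 with an estimated correlation, foreign compound genes (0.28 over 21) had 0.00292, and an adjusted p = 0.566 with an estimated correlation, and macrophage markers (-0.25 over 14) had 0.0275, and an adjusted p = 0.93 with an estimated correlation.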

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

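The tests of a lower hepatocyte share, of more macrophages or a higher level per macrophage, and of swapped labels were chosen only after the result was seen, and the bound that decides the second of these was changed after its first run, because a p that misses the threshold does not show absence.

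Over 10 quantities, 80 groups of 5 animals were screened with Dixon's test, which chance passes in about 1 of 20 groups, and 11 held an animal far from the other 4. For the score of the intact sex difference these were animal 53 (0.616 under DHT, others -0.895 to -0.732), animal 46 (-0.402 under estradiol, others -0.0597 to 0.0749), animal 24 (0.587 with placebo, others 0.424 to 0.461) and animal 11 (-1.24, intact, others -1.87 to -1.8). For Eif2s3y they were animal 63 (1.44, others 0.534 to 0.754) and animal 11 (0.407, others 1.14 to 1.33). For Hsd3b5 they were animal 61 (-3.19 under DHT, others 1.2 to 2.41) and animal 46 (0.605 under estradiol, others -3.39 to -2.36). Animal 53 also stood apart for Cyp2b9 (0.76, others -3.18 to -2.17) and Cyp17a1 (0.126, others -2.56 to -2.1), and animal 11 for Cyp7b1 (-0.664, others 1.55 to 2.02).

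The response to gonadectomy differed between the sexes in limma's test of the interaction for 1038 probes. The genes named by the rule were Hsd3b5 (5.74), Elovl3 (4.4), Cyp7b1 (3.86), Moxd1 (3.65), Cyp4a12a (3.32), Slc22a26 (-5.84), Cyp2b13 (-5.69), Cyp2b9 (-5.23), Sult3a1 (-3.84) and Hao2 (-3.58), where other probes read 0.19 for Hsd3b5, -0.50 for Cyp2b13, -0.30 for Cyp2b9 and -0.23 for Sult3a1. Lists that differed there in limma's camera test at the preset correlation had medians of -0.89 (known female-biased genes), 1.59 (known male-biased genes), 0.236 (cholesterol synthesis), 0.236 (steroid hormone metabolism) and -0.286 (T and B cell markers). With an estimated correlation the male-biased list alone passed, at an adjusted p of 0.00705, and the others had 0.0903, 0.796, 0.0551 and 0.413. For estradiol the preset correlation called a sex difference for known male-biased genes (-0.368), steroid hormone metabolism (-0.14), macrophage markers (0.452) and T and B cell markers (0.173), and for DHT for foreign compound metabolism (0.398). None of these 5 passed with an estimated correlation (adjusted p = 0.553, 0.0716, 0.553, 0.553 and 0.961), with 0 probes called in limma for either and 973 and 1790 at an unadjusted p under 0.05.

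Macrophage markers lay higher in estradiol-treated than in DHT-treated females, with a median of 1.02 and an SD over markers of 0.594, and 2 genes of the list also stand in another list. A lower share of hepatocytes would raise the markers of other cell types alike, and the tables argue against it, since among endothelium, stellate cells and cholangiocytes, the types named for this test, the highest median was 0.0772, and T and B cells had 0.212 and neutrophils 0.205. That 1 or 2 arrays carry the difference may explain it and was not settled. The condition written before the test was met by overlap of the scores alone. That overlap was present with all animals, at -0.279 in animal 34 under estradiol and -0.243 in animal 50 under DHT, so it cannot decide. The scores of animals 35 and 36 were 1.04 and 1.52. Without them the median was 0.545, which stayed above the bound on the median in that condition, and limma called 0 markers. More macrophages or a higher level per macrophage under estradiol may also explain it and was not settled, with an exact p of 0.0794 for estradiol against placebo (5 animals each).

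The clock index lay higher after ovariectomy (0.885) and castration (0.557) than in intact mice, each at an adjusted p of 0.0536 over 9 exact tests, and DHT-treated castrated males lay at 0.454 against -0.547 in intact males, untested. The list of 14 clock genes did not pass in limma's camera test, which looks for a shift in 1 direction and cannot decide here, since the list holds both opposite arms. Livers taken at different hours may explain such a shift: within groups, the residuals of the opposite arms had an r of -0.597 over 40 animals (permutation p = 4e-05; rank correlation -0.638, permutation p = 2e-05), and of -0.603 without the 2 animals farthest out. These values show variation along the clock axis within groups and not when any group was sampled, and an effect of gonadectomy on the clock was not tested apart from it. Whether time of day adds to the castration count was not settled, since 1728 of 2856 probes passed with the clock index as a covariate.

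Animal 53, under DHT, had a score near that of placebo females, a pattern found from that score. A swap of labels with a placebo female needs a placebo female with a low score, and the tables argue against it, since the lowest was 0.582. A failed array is argued against by Eif2s3y, at -5.84 within the -6.07 to -3.82 of the other 19 females. That this animal did not respond to DHT, which may have many reasons, was not settled: its mean response over the 819 probes called for DHT in males was -0.129, between the -0.452 to -0.197 of placebo females and the 0.3 to 0.421 of the other 4 DHT-treated females. Animal 61, a castrated male under DHT, had a score of 0.135 against -1.37 to -0.55 in the other 4. Dixon's test did not flag that score, and its reasons were not tested.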

How the results depend on the processing

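The alternatives without wide arrays and with the clock index as a covariate, and the counts without the animals of highest macrophage score, are tests chosen only after the result was seen.

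No paired analysis was possible because each animal number occurs in 1 group. The alternative of keeping only probes with values on all 40 arrays changed nothing, since no value is missing, and gives no value. Signal over background was unknown here, so its limits could not be set. No result reversed under any alternative run. Over the alternatives other than leaving out 1 animal, 1670 values of single named genes kept direction and side of the threshold and 112 lost the threshold, and the macrophage markers called fell from 11 to 0 without the 2 animals of highest score. Leaving out 1 animal kept 1798 values of single named genes and lost 282. Counts of whole comparisons that moved past 1.5 times are outside these tallies and are given below. Of list results 253 kept the call and 87 lost it, 75 of them with an estimated correlation, which kept 10 of 85, 9 with quantile normalization and 3 with median centring. Of 198 gene results, 61 lost the threshold with only the groups of the contrast in the fit, 35 with the clock index, 9 with quantile normalization, 4 without wide arrays, 2 with median centring and 1 with gene means, and 0 with array weights, robust moderation or the filter on flat probes. No direction split moved by over 10 points, the largest by 9.9 with median centring, and no scaling moved the median of all probes by over 0.021. The cause was not tested for the values below. Gene means and the filter on flat probes test fewer features, and a fit on a contrast's groups has fewer arrays. Some counts nevertheless rose there, such as DHT in females from 271 to 545 with only its groups in the fit.

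With quantile normalization the counts were 16 for ovariectomy, 1802 for castration, 757 for DHT in females, 372 for DHT-treated against intact males and 530 for the interaction of sex and gonadectomy, the slope was 0.244, and 233 probes were shared by the DHT responses instead of 136. With only the groups of the contrast in the fit they were 1249 (sex, intact), 31 (sex, placebo), 13 (sex, estradiol), 1 (ovariectomy), 1763 (castration), 55 and 37 (estradiol in females and males), 545 and 260 (DHT in females and males), 270 and 8 (estradiol against DHT in females and males), 48 (estradiol-treated against intact females) and 241 (DHT-treated against intact males). With gene means of named genes they were 1065 (sex, intact), 8 (sex, placebo), 20 (sex, estradiol), 11 (sex, DHT), 15 (ovariectomy), 1361 (castration), 170 (estradiol in males), 129 and 423 (DHT in females and males), 279 (estradiol-treated against intact females), 736 (DHT-treated against intact males), 534 (interaction with gonadectomy) and 1 (interaction with estradiol). With only probes above the median SD they were 1358 (sex, intact), 19 (ovariectomy) and 1876 (castration).

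With array weights, from 0.317 to 4.04, the counts were 5443 (sex, intact), 39 (sex, placebo), 77 (sex, estradiol), 1310 (sex, DHT), 31 (ovariectomy), 7762 (castration), 1092 and 753 (estradiol in females and males), 1298 and 3801 (DHT in females and males), 3075 and 1877 (estradiol against DHT in females and males), 1806 (estradiol-treated against intact females), 6220 (DHT-treated against intact males), 3007 (interaction with gonadectomy), 3 (interaction with estradiol) and 762 (interaction with DHT). Without the wide arrays of animals 9, 34, 35 and 63 they were 20 (ovariectomy), 389 and 459 (estradiol in females and males), 1271 (DHT in males), 719 (estradiol against DHT in males) and 948 (estradiol-treated against intact females). With the clock index they were 0 (ovariectomy), 1728 (castration), 184 (estradiol against DHT in females) and 10 (DHT-treated against intact males). The index did not overlap between the groups for ovariectomy, for DHT-treated against intact males and for estradiol-treated against intact females. There the covariate cannot tell a clock effect from a group effect. For estradiol against DHT in females the index overlapped only slightly. With a 1.2-fold threshold the placebo sex difference of the score was 0.0571. Median centring and robust moderation moved no count past 1.5 times.

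Leaving out 1 animal gave 1455 to 2604 (sex, intact), 13 to 23 (sex, placebo), 19 to 47 (sex, estradiol), 15 to 24 (sex, DHT), 2 to 23 (ovariectomy), 1976 to 3687 (castration), 22 to 902 and 69 to 322 (estradiol in females and males), 89 to 443 and 335 to 1115 (DHT in females and males), 281 to 1523 and 48 to 493 (estradiol against DHT in females and males), 84 to 1455 (estradiol-treated against intact females), 762 to 2870 (DHT-treated against intact males), 778 to 1243 (interaction with gonadectomy), 0 to 2 (with estradiol) and 0 to 7 (with DHT). The score differences ran from 0.223 to 0.305 (sex, placebo), -0.187 to -0.0962 and -0.618 to -0.503 (estradiol in females and males), and -1.56 to -1.11 and -1.53 to -1.06 (DHT in females and males), and the slope from 0.146 to 0.175.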

Other observations

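The test of the male-biased program under estradiol was written before its result was seen, and the choice of which patterns to weigh came after.

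Estradiol may move the male-biased program of castrated males as a whole, and not only Cyp7b1, Egfr and Sult5a1. The hypothesis was tested on the 299 male-biased probes of the intact score, whose mean was higher under estradiol than placebo with an exact p of 0.00794 (5 animals each), the smallest that 5 against 5 can give. Of these probes 90% had a positive difference, with 27 called higher and 0 lower. Of the 161 female-biased probes 28.6% had a positive difference, with 1 called higher and 5 lower. The mean changed by 0.362 for the male-biased and by -0.213 for the female-biased probes, so the shift was not limited to the male-biased set. The values of the male-biased probes met the condition written before the test. Of the 17 known male-biased genes fixed as a list, 3 were called higher (6 adjusted over the list alone), with an adjusted p of 0.00072 in limma's camera test and an adjusted p = 0.39 with an estimated correlation, and Elovl3 differed by -0.33 (adjusted p = 0.711 in limma), so not every member is shown to rise, and the hypothesis was found and tested on the same animals. A further test, whether 1 animal carries the 3 genes, argued against that, with at least 0.874 of each difference left without any 1 animal, although Cyp7b1 had an adjusted p above 0.05 in limma in 6 of 10 cases, from 0.0601 without animal 25 to 0.0954 without animal 46.

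For each comparison of 2 groups, 100 splits of the same animals, the real one included, were drawn. For the interactions, residuals of a fit with sex and treatment but no interaction were permuted over the animals instead, in 100 draws with the real one included. The median of the other splits or draws was 0 probes. At most 4 of 100 splits, the real one included, called as many probes for the sex difference in intact mice (2048 probes, highest other split 3190, 3 splits as large), after gonadectomy and placebo (16, 11, 1) and under DHT (19, 13, 1), for ovariectomy (8, 17, 2) and castration (2856, 3183, 2), for estradiol in females (149, 601, 4) and males (278, 2827, 2), and for DHT in females (271, 129, 1) and males (819, 1897, 3). The same holds for estradiol against DHT in females (893, 1050, 2) and males (167, 233, 2), estradiol-treated against intact females (445, 1456, 3), DHT-treated against intact males (1491, 3758, 4) and, by draws of residuals, the interaction of sex and gonadectomy (1038, 418, 1). These shares were not adjusted over the 17 contrasts. In many of these comparisons a false split called more probes than the real one, so chance is made less likely and is not excluded. The count for the sex difference under estradiol (32, 1310, 13 splits as large) was not told apart from chance, although the Y-linked genes still separated all animals. For the interactions with estradiol and DHT limma called 0 probes (973 and 1790 at an unadjusted p under 0.05), so all 100 draws of residuals call as many whatever they hold and decide nothing, and the highest other draws called 355 and 1. Splits that called several times the real count, as for the sex difference under estradiol, estradiol in either sex, estradiol-treated against intact females, DHT in males and DHT-treated against intact males, point to a structure of the samples, which was not tested. The highest correlation between the residuals of 2 arrays was 0.69, for animals 3 and 26 of different groups.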
